A study of Equus caballus with 20 samples.

How the data were processed

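Muscle RNA of 5 French Trotter horses with recurrent exertional rhabdomyolysis (RER) was compared with pooled RNA of 10 healthy controls in gluteus medius and longissimus lumborum. Per the labels, RNA was extracted with TRIZOL, 5 µg were amplified and labelled indirectly through amino-allyl nucleotides, and each RER sample was hybridised with the control pool of its muscle on 2 oligonucleotide arrays with the dyes exchanged, whose results were averaged before statistics. The deposited values are log2 ratios of the 2 channels, 24493 probes by 20 arrays, in a table the authors had already normalized by a method that the sources used here do not state. The log2 scale was read from the values, which run from a floor of -6.6439 (the log2 of a ratio of 0.01, 707 values) to 9.4043, with array medians within 0.0444 of 0. Scanner, background correction and the filter that left blanks were not stated.

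The number of measured probes parted the arrays into 10 dense ones (22032 to 24050 values, 2 to 49 exact zeros) and 10 sparse ones (8966 to 17708 values, 208 to 494 exact zeros). The dense arrays are those of gluteus horses 1, 2 and 3 and longissimus horses 1 and 2. The dye pattern shared between arrays was checked against the labelled dye and matched in 20 of 20 arrays. It follows the channels of the ratio and does not show which RNA was in them.

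The planned orientation rule was to turn the Cy3 array of a pair whose 2 arrays correlate below 0. Of the 10 pairs, 6 correlated above 0 and 4 below (gluteus horse 2 at -0.206 and horse 3 at -0.268, longissimus horse 1 at -0.269 and horse 2 at -0.322). Since the dye pattern matched every label and the pairs differ in sign within 1 deposited table, the deposited orientation was kept for all arrays, a departure from the rule read pair by pair that was decided before any gene was tested. The turned version was run as an alternative. In it the dye pattern of a turned pair adds up instead of cancelling, so its values may hold dye bias. The labels do not state the direction of the ratio, and RER over pool is the likely reading.

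Each array was centred on its median, and the 2 arrays of a horse and muscle were averaged where both had a value. Of the probes, 13692 carried a gene symbol (12187 symbols) and 10801 carried none. Symbols are written in the mouse style (such as Atp2a1) or in capitals (such as ATP2A1). How well either kind of probe matches horse RNA was not tested, which limits every ratio and every absence of a call. Probes of the same symbol were averaged, giving 22988 features. Features with at least 4 of 5 horses in each muscle were tested, 10176 in all, 5918 with a symbol and 4258 without, and 915 of the 10176 average more than 1 probe. The 2 muscles come from the same horses according to the labels, and as a check the deviations from the muscle means correlated within horse at 0.58, 0.304, -0.0976, 0.0206 and -0.00245 in horses 1 to 5.

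Ratios were tested against 0 with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with moderated variances and Benjamini-Hochberg adjustment at 0.05. Gluteus, longissimus and their difference came from a single fit of the 10 horse by muscle values with muscle as the factor, and the mean of both muscles from a fit of the 5 per-horse means (10063 features). The control pool is 1 sample per muscle, so no test includes the spread among controls. The agreement between muscles is a correlation across features and carries no p.

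Of 24 gene lists, 22 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated from the data and with fry. The lists were glycolysis, glycogen metabolism, fatty acid uptake and oxidation, TCA cycle and mitochondrial carriers, respiratory chain, calcium handling and excitation-contraction coupling, fast and slow fibre sarcomere, endoplasmic reticulum stress, heat shock proteins, extracellular matrix, macrophages, lymphocytes and neutrophils, muscle regeneration, antioxidant defence, proteasome and muscle atrophy, lysosome and autophagy, cytosolic ribosomal proteins, endothelium, adipocytes, nerve and Schwann cells, and smooth muscle and pericytes. Erythrocyte markers (3 on the array, 2 tested) and mitochondrially encoded genes (8 on the array, 0 tested) had too few members. The tested erythrocyte markers Alas2 and Klf1 had gluteus log2 ratios of -0.097 and 0.031 and longissimus ratios of 0.059 and -0.099.

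The named genes follow a rule. In each comparison they are the genes past the threshold with 1 sign in every horse, filled to 10 in each direction by the smallest p among genes with 1 sign in every horse, and up to 4 members of each list with the smallest p. As none passed, all were filled in by p, and some list members are left unnamed for length. The tests, lists, thresholds and naming rule were chosen before the data were examined.

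The procedure was tested on simulated data with 50 features (49 in 1 case) shifted at each of 4 sizes. Shifts of 1.5-fold were recovered in 66% (gluteus), 60% (longissimus), 74% (both) and 26% (difference) of features, and shifts of 2-fold in 80%, 78%, 92% and 70%. False calls were 10 of 179, 4 of 172, 7 of 187 and 15 of 161. In 1 simulated set a list shifted alike in every horse was found in 3 of 3 comparisons. The simulated genes were independent, so this does not show how the list test behaves where genes of a list correlate.

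Alternatives were no centring, scaling to a common spread, a single dye orientation, complete features, a looser missing-value rule, single probes, removal of the 50% noisiest features, a robust variance model, no variance moderation, each muscle fitted alone, the horse as a random or fixed replicate block, and each horse left out in turn. Some were added after the values had been seen. These were the turned orientation as an alternative (the planned rule read pair by pair), dense or sparse arrays only, the array group as a term and floored values as missing. Also added then was the estimated correlation for lists called with a horse left out or on dense or sparse arrays. It was not run for the mean of both muscles on dense or sparse arrays.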

Results

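Recurrent exertional rhabdomyolysis (RER) is a disorder of the horse in which bouts of exercise are followed by stiffness and breakdown of muscle fibres. The series asked which transcripts differ in muscle of affected French Trotters, with energy metabolism and calcium handling named as its themes. It drew on 15 horses, 10 healthy controls and 5 with RER, and on biopsies of 2 muscles, the gluteus medius of the hindquarter and the longissimus lumborum of the back. RNA of each RER horse was hybridised against the pool of control RNA from the same muscle on oligonucleotide arrays, with 2 dye-swapped arrays per horse and muscle, 20 arrays in all. The horse was the replicate, with 5 horses in each muscle, and their number limits the precision of every value below. The arrays held between 8966 and 24050 measured log2 ratios for 24493 probes. Grouped here by that number, 10 arrays were dense, with at least 22032 values, and 10 sparse, with at most 17708. Gluteus horses 1, 2 and 3 and longissimus horses 1 and 2 lay on dense arrays, and the other horses of each muscle on sparse arrays.

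Signs are those of the deposited ratios, and their likely direction is RER over control pool, since RER RNA is the first channel of every array and a test sample is usually divided by its reference. The direction is not settled, because the labels do not state it and arrays of the same dye orientation against the same pool ran opposite ways (the Cy3 arrays of gluteus horses 2 and 4 correlated at -0.341 across probes). With every sign turned, each value below keeps its size and the positive and negative counts change places. All ratios are against pools that count as 1 control sample per muscle, so the tests leave out the spread among control horses. Standard errors of genes come from the moderated fit. For a single muscle they use a spread shared by both muscles, not that of its own horses alone.

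In gluteus the gene with the smallest p was Eif4h, and no gene passed the threshold. Eif4h and Eif4a2, partners in the unwinding of mRNA at translation initiation, had log2 ratios of -0.41 ± 0.072 (SE, n = 5) and -0.40 ± 0.11 (SE, n = 5). Calm2, a calmodulin gene, was at -0.40 ± 0.11 (SE, n = 5), below 0 in every horse. Ebna1bp2, a nucleolar factor of ribosome assembly, had the most negative mean of the named genes at -1.27 ± 0.34 (SE, n = 5). Ratios below 0 in every horse with a value were also found for Wscd1 at -0.59, Tcf7 at -0.47, Trh at -0.42, Ugcg (glucosylceramide synthase) at -0.34, Setd5 at -0.33 and Mtch1, a mitochondrial outer membrane protein, at -0.28. On the positive side stood Fmnl3 at 0.45 ± 0.15 (SE, n = 4), Grb14, an adaptor that restrains insulin receptor signalling, at 0.40 ± 0.12 (SE, n = 4), Slc2a9, a urate transporter, at 0.34 and Cnp at 0.30. Shank3 at 0.29, Gpr6 at 0.26, Sae1 at 0.26, Tbc1d14 at 0.21, Nfe2 at 0.20 and Vps13a at 0.19 completed that side. None of these 20 genes passed the threshold, and they stand here for having 1 sign in every horse and the smallest p.

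Of 10176 features tested in gluteus (genes, or single probes without a gene symbol), limma with Benjamini-Hochberg adjustment called 0 at an adjusted p under 0.05, and the lowest adjusted p was 1. At an unadjusted p under 0.05 there were 187 features, 64 above and 123 below 0, where chance alone gives about 509. Without variance moderation 0 features passed as well. With gluteus fitted alone, 510 features reached an unadjusted p under 0.05 and 0 passed the threshold. The 95% confidence interval lay inside a 2-fold change in either direction for 96.8% of features, with a median standard error of 0.118. Arrays of a single dye orientation called 2 features (Cy3, both unnamed probes) and 4 (Cy5: the water channel Aqp3 at 1.02, Bmp8a at -4.28, the proteasome subunit Psmb4 at -0.70 and an unnamed probe). These were 5 features in all, 1 of them called in each orientation, and all 5 had opposite signs on the Cy3 and Cy5 arrays (Aqp3 at -0.86, Bmp8a at 3.21 and Psmb4 at 0.25 in Cy3), so they follow the dye. Sparse arrays alone called 1 unnamed probe, and the genes called in these settings were named after their values were seen.

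The proteasome list lay below 0 as a group in gluteus. Its median log2 ratio was -0.12, 20 of 24 measured members lay below 0, and camera with a preset correlation gave an adjusted p of 0.0127, the only one of 22 lists past the threshold. Its call was lost with an estimated correlation between genes (adjusted p = 0.825). Psmb4 stood at -0.22 ± 0.10 and Psmb7 at -0.17 ± 0.10, both below 0 in 4 of 5 horses, Psma6 at -0.33 ± 0.20 and Psmd11 at -0.11 ± 0.071. Psmb4 had opposite signs in the 2 orientations (0.25 in Cy3, -0.70 in Cy5), so its mean may hold an unequal dye effect. The list was below 0 on dense arrays (median -0.22, adjusted p 0.00136, and 0.0156 with an estimated correlation) and near 0 on sparse arrays (0.0072), and without horse 1 or horse 2 it no longer passed, with adjusted p of 0.142 and 0.0974. With the Cy3 arrays of the 4 pairs that correlate below 0 turned, the list stood at -0.029 and was not called (adjusted p 0.368). In that setting TCA cycle (-0.17), respiratory chain (-0.10), extracellular matrix (0.090) and ribosomal genes (0.081) were called, the last 2 with a sign opposite to the medians given below. Dye effects add up in the turned pairs, so these calls may hold dye bias.

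Genes of the TCA cycle and mitochondrial carriers had a median of -0.11 with 18 of 19 members below 0 (adjusted p = 0.172, and 0.86 with an estimated correlation). It passed without horse 3 (median -0.19, 19 of 19 below 0, adjusted p 0.0382) and without horse 5 (-0.13, 0.0255), but not there with an estimated correlation (0.855 and 0.863). Sdha, a subunit of succinate dehydrogenase, was at -0.23 ± 0.13. The horses differed, with medians of -0.36 and -0.37 in horses 1 and 4 against 0.11, 0.080 and 0.079 in horses 2, 3 and 5. Nuclear genes of the respiratory chain had a median of -0.053 over 40 members, with Uqcrb at -0.35 ± 0.16 and below 0 in every horse. Fatty acid uptake and oxidation had a median of -0.093, and Cpt1b, which admits fatty acids to the muscle mitochondrion, was at -0.26 ± 0.11. Glycolysis (0.016) and glycogen metabolism (0.036) lay near 0, with Aldoa at -0.19 ± 0.20 and Phkb at 0.28 ± 0.16.

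Cytosolic ribosomal proteins parted with the array groups in gluteus. Each group there holds other horses, so array group and horse cannot be told apart. Horse 3, dense in gluteus and sparse in longissimus, had ribosomal medians of -0.45 and -0.009. Horse 2, dense in both, had -0.45 and -0.025. Over all 5 gluteus horses the ribosomal median was -0.070 (adjusted p = 0.172, and 0.926 with an estimated correlation). On dense arrays it was -0.39 with 54 of 57 members below 0, and on sparse arrays it was 0.35 with 54 of 55 above 0. Extracellular matrix genes parted likewise, at -0.18 on dense and 0.32 on sparse arrays around an overall median of -0.037 (adjusted p = 0.843, and 0.926 with an estimated correlation). Camera called each of these 4 shifts (adjusted p 2.42e-28 and 5.21e-10 for the ribosomal list, 4.73e-05 and 0.00431 for the matrix list), within fits of 3 dense and 2 sparse horses. With the correlation estimated in each array group the ribosomal calls held (0.0156 and 0.000837) and the matrix calls did not (0.0932 and 0.36). Leaving out horse 4 or horse 5 from the whole set took the ribosomal median to -0.22 or -0.16 with a call (adjusted p 4.02e-12 and 0.000163), and leaving out horse 4 did so for the matrix list (-0.099, 0.000358). With an estimated correlation these 3 calls were lost (0.405, 0.863 and 0.217). Without horse 4 the endoplasmic reticulum stress list passed too, at -0.066 with 9 of 9 members below 0 (0.00751, and 0.0689 with an estimated correlation). The respiratory chain list likewise passed without horse 3 or horse 5, at -0.12 each (0.0382 and 0.00365, and 0.855 and 0.863 with an estimated correlation). Col4a1, a basement membrane collagen, was at -0.28 ± 0.11 over all horses.

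Among calcium handling genes 18 of 29 members lay below 0 (median -0.035, adjusted p = 0.692), and besides Calm2 the store-operated calcium sensor Stim1 was at -0.23 ± 0.086, below 0 in each of its 4 horses. Fast and slow fibre sarcomere genes had medians of -0.024 and -0.040, with Tnni1, the slow skeletal troponin I, at 0.22 ± 0.13 and Myl3 at -0.18 ± 0.11. Endoplasmic reticulum stress genes were at -0.063 with Hspa5 at -0.36 ± 0.41, heat shock proteins at -0.041, and antioxidant genes at -0.0092 with Prdx2 at 0.14 ± 0.071 and Nfe2l2 at -0.19 ± 0.10. Muscle regeneration genes had a median of -0.027, with the fetal and cardiac actin Actc1 at 1.21 ± 0.85 and desmin (Des) at -0.16 ± 0.11, most of it from horse 4 at -0.54. Markers of other cells had medians of -0.046 for macrophages, 0.016 for lymphocytes and neutrophils, 0.0067 for endothelium, 0.016 for adipocytes and -0.0035 for nerve, with lysosome and autophagy genes at 0.0045. Horse 4 differed from these, at 0.23 for macrophages, 0.19 for adipocytes, 0.25 for nerve and 0.58 for extracellular matrix, beside a TCA cycle median of -0.37. The smooth muscle and pericyte list was at -0.085, with 5 of 5 members and the median of 5 of 5 horses below 0 (adjusted p = 0.461). Il7r was at 0.16 ± 0.095 and the endothelial cadherin Cdh5 at 0.15 ± 0.079. Adjusted over the list alone, 0 members of any list passed in gluteus. Median, mean and test did not share a sign for 9 lists there (glycolysis, both sarcomere lists, extracellular matrix, muscle regeneration, antioxidant defence, lysosome, adipocyte and nerve).

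**Figure D1:**
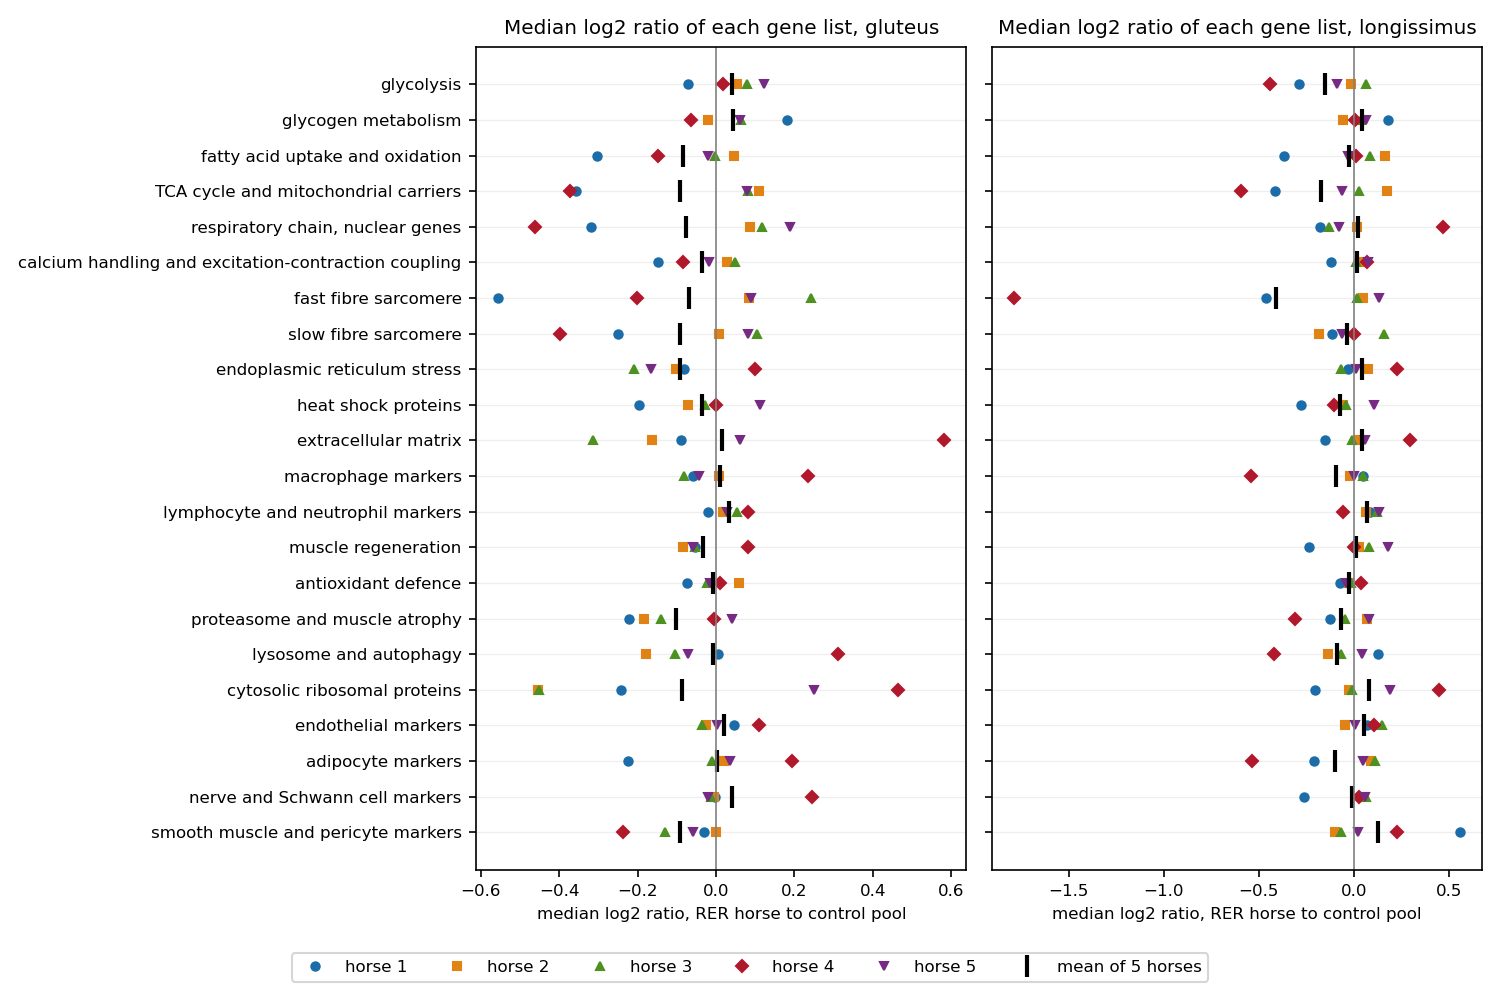
Each point is the median log2 ratio (RER horse to control pool, x axis) of 1 gene list (y axis) in 1 horse, for gluteus (left) and longissimus (right), and the bar is the mean of 5 horses. In both muscles the TCA cycle list sits lowest in horses 1 and 4 (-0.36 and -0.37 in gluteus, -0.41 and -0.60 in longissimus).

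In longissimus, too, no gene passed the threshold. Myl3, the slow and ventricular essential myosin light chain, was at -0.36 ± 0.11 (SE, n = 5). Sh3pxd2b, an adaptor of podosomes, had the smallest p at -0.58 ± 0.10 (SE, n = 5), and Prkcsh, the beta subunit of glucosidase II, was at -0.67 ± 0.20 (SE, n = 5). Ppm1h at -0.53, Icam4 at -0.41, Rap1gds1 at -0.39, As3mt at -0.36, Arf3 at -0.32, Shq1 at -0.31 and Dnase1l2 at -0.27 were also below 0 in every horse with a value. Above 0 in every horse with a value stood Kbtbd8 at 0.86 ± 0.19 (SE, n = 4), the retromer subunit Vps29 at 0.62 ± 0.14 (SE, n = 4) and Pnpt1, an RNA-processing enzyme of mitochondria, at 0.31 ± 0.074 (SE, n = 5). They were joined by Rnf11 at 0.52, Ssbp2 at 0.52 (1.51 in horse 4, at most 0.32 in the others), Meox2 at 0.50, Magoh of the exon junction complex at 0.43, Pgm2 at 0.42, Cit at 0.30 and the splicing factor Prpf6 at 0.30. None of the 20 passed the threshold.

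The limma test called 0 of 10176 features in longissimus, with a lowest adjusted p of 0.827. At an unadjusted p under 0.05 there were 426 features, 122 above and 304 below 0, against about 509 by chance, and without variance moderation 0 passed. With longissimus fitted alone, 147 features reached an unadjusted p under 0.05 and 0 passed the threshold. The confidence interval lay inside a 2-fold change for 94.5% of features. Arrays of a single orientation gave other counts, 2 features (Cy3, Aqp3 at -1.23 and an unnamed probe) and 89 (Cy5, 30 above and 59 below 0), and 87 of these 90 features had opposite signs on the Cy3 and Cy5 arrays. The other 3 were Sh3pxd2b (-0.55 in Cy3 and -0.61 in Cy5, called in Cy5 at an adjusted p of 0.0337), Rev3l (0.18 and 0.73, called in Cy5 at 0.0411) and an unnamed probe. Sparse arrays alone gave 2 (Pnma2 at -1.97 and an unnamed probe, chosen after their values were seen).

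**Figure D2:**
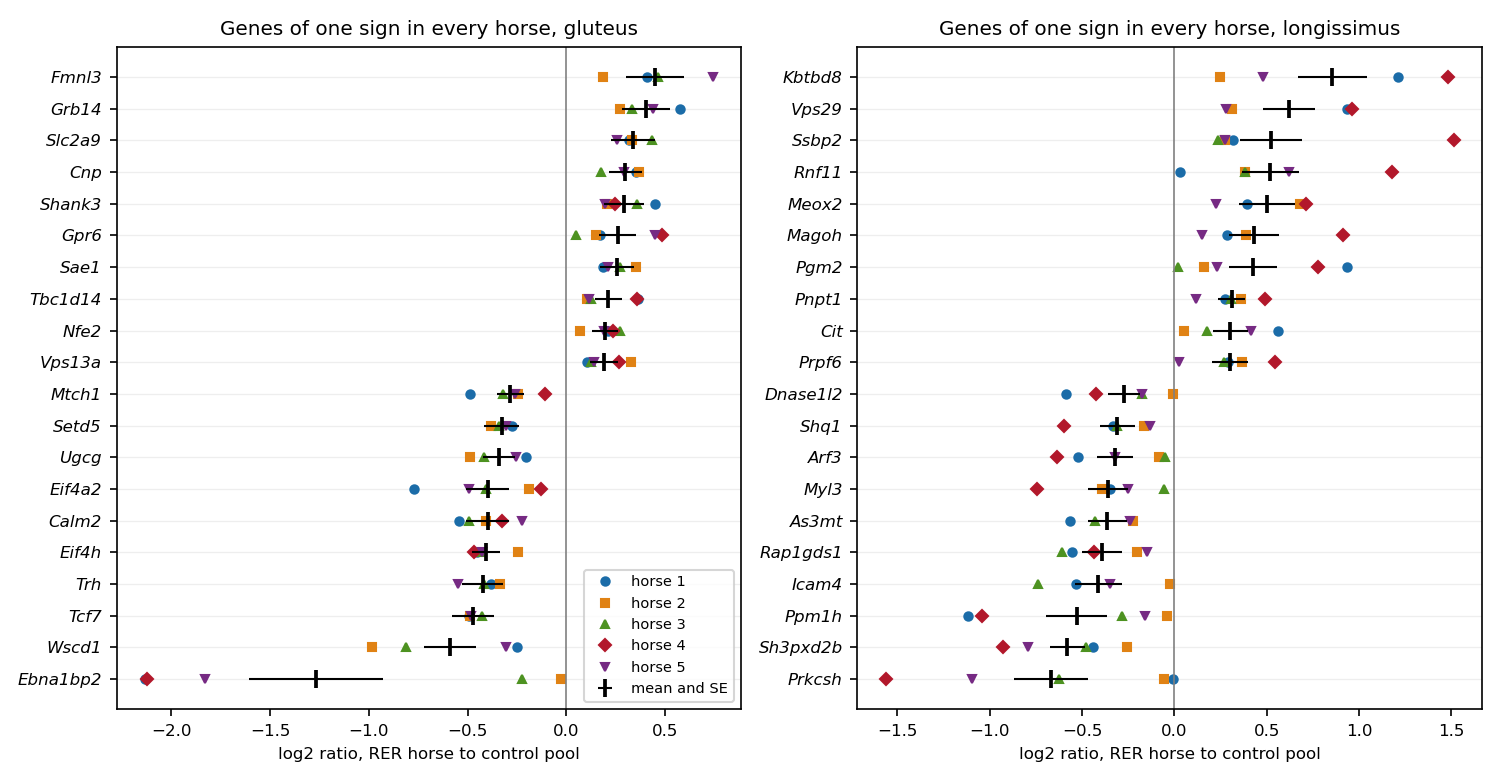
Log2 ratios (RER horse to control pool, x axis) of the 20 genes named by rule in gluteus (left) and longissimus (right), with 1 marker per horse and the mean with its standard error in black. The standard error is that of the moderated fit, which shares its spread over both muscles. Every marker of a gene lies on 1 side of 0, and none of the genes passed the adjusted threshold.

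Enzymes of the TCA cycle and glycolysis lay mostly below 0 in longissimus without any list passing the threshold. The TCA cycle list came closest, with a median of -0.17, 14 of 19 members below 0 and an adjusted p of 0.223 (0.971 with an estimated correlation). Idh2, the mitochondrial isocitrate dehydrogenase that yields NADPH, was at -0.33 ± 0.11 and below 0 in every horse, Slc25a11 at -0.27 ± 0.12 and Sdhc at -0.74 ± 0.37. Glycolysis had a median of -0.10 with 12 of 14 below 0 (adjusted p = 0.616). Its members differed, with Pgam2, the muscle phosphoglycerate mutase, at -0.62 ± 0.20, Aldoa at -0.47 ± 0.20 and Pfkm at 0.37 ± 0.17. The respiratory chain list was split, 22 members above and 18 below 0 with a positive median of 0.041 and a negative mean. Ndufb7 at -0.65 ± 0.25, Ndufs3 at -1.17 ± 0.54 and Cox6b1 at -0.23 ± 0.093 were below 0 in every horse, while Cox6c was at 0.42 ± 0.18. Fatty acid oxidation had a median of -0.11 with Hsd17b10 at -0.61 ± 0.26, and glycogen metabolism one of 0.0077.

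Calcium handling genes had a median of -0.031 in longissimus (17 of 29 below 0, adjusted p = 0.923). Hrc, the histidine-rich calcium-binding protein of the sarcoplasmic reticulum, was at -0.46 ± 0.21 and below 0 in every horse. Cacna2d1, the alpha-2/delta-1 calcium channel subunit, was at 0.16 ± 0.070 and above 0 in every horse, with Camk2b at 0.30 ± 0.12 and the muscle calpain Capn3 at -1.31 ± 0.59. The fast fibre list had the lowest median of all, -0.23 over 6 members (adjusted p = 0.794), with troponins Tnnc2 at -1.33 ± 0.68 and Tnnt3 at -0.72 ± 0.37, and the slow fibre list one of -0.034. Horse 4 carried much of this, with Tnnt3 at -2.95 and Ndufs3 at -4.56 in that horse against lowest values of -0.33 and -0.97 in the other horses. The same horse stood alone for Sdhc (-3.09), Ndufb7 (-2.12), Hrc (-1.63) and Cacna2d1 (0.37).

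The proteasome list had a median of -0.14 in longissimus (adjusted p = 0.616), with Psmd8 at -0.74 ± 0.29, Psmc5 at -0.56 ± 0.26 and Psmd12 at 0.28 ± 0.15. Horse 4 stood alone for Psmd8 (-2.41) and Psmd12 (1.05), and likewise for Rpl10 (-4.10) and Cd68 (-1.93) below. Ribosomal proteins were balanced, 29 above and 28 below 0, with Rpl30 at 0.37 ± 0.15 and Rpl10 at -1.06 ± 0.47. Heat shock proteins had a median of -0.083 with Hspb6 at -0.50 ± 0.22, endoplasmic reticulum stress genes 0.023, antioxidant genes -0.0083 with Hmox1 at -0.18 ± 0.086, and regeneration genes -0.030 with the satellite cell factor Pax7 at 0.16 ± 0.079. Extracellular matrix genes stood at 0.051 with Lama2 at -0.30 ± 0.13. The macrophage list was at -0.030 with Cd68 at -0.45 ± 0.24, and the remaining lists were at 0.0039 (lymphocytes and neutrophils), 0.026 (endothelium), -0.044 (adipocytes), -0.0047 (nerve), 0.052 (smooth muscle) and -0.049 (lysosome). Adjusted over the list alone, 0 members passed, the lowest such adjusted p being 0.0786 for Myl3 in the slow fibre list. Median, mean and test did not share a sign for 5 lists in longissimus (glycogen, respiratory chain, calcium handling, lymphocyte and neutrophil, ribosomal). On dense arrays alone the ribosomal list passed at a median of -0.12 (adjusted p = 0.00115, and 0.72 with an estimated correlation). Without horse 4 the respiratory chain list passed with a median of -0.095 (adjusted p = 0.0339, and 0.958 with an estimated correlation).

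When the muscles of each horse were averaged, proteasome and TCA cycle genes lay below 0 as groups. The proteasome list had a median of -0.10, 18 of 24 members below 0 and an adjusted p of 0.0112 by camera, and the TCA cycle list a median of -0.15, 15 of 19 below 0 and an adjusted p of 0.0329. Neither call held with an estimated correlation (adjusted p = 0.318 and 0.822). Of the 5 sets with 1 horse left out, the proteasome list passed with an estimated correlation in 1, without horse 5 (median -0.12, 19 of 24 below 0, adjusted p 0.0183). The proteasome genes Psmd8 at -0.24 ± 0.090 and Psmc1 at -0.16 ± 0.064 were below 0 in every horse with both muscles, with Psmd4 at -0.49 ± 0.21 and Psmc5 at -0.40 ± 0.18. Psmd8 leaves out horse 4, which lacks a gluteus value and stood at -2.41 in longissimus, where the mean over 5 horses was -0.74. Of the TCA cycle list, Sdhc at -0.52 ± 0.26 was below 0 in every horse (-1.81 in horse 4), with Slc25a3, the phosphate carrier, at -0.40 ± 0.24, Idh2 at -0.18 ± 0.085 and Sdha at -0.17 ± 0.091. Per horse, the TCA cycle medians were -0.41 in horse 1 and -0.51 in horse 4, against 0.14, 0.020 and -0.020 in horses 2, 3 and 5. Other lists moved in the same horses, as the fast fibre medians were -0.51 in horse 1 and -0.92 in horse 4, against 0.083 to 0.13 elsewhere, and the extracellular matrix median was 0.72 in horse 4, against -0.14 to 0.076.

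The calls depended on which horses and arrays were kept. With the Cy3 arrays of the 4 pairs turned, the proteasome and TCA cycle medians were -0.077 and -0.098 and neither passed by camera (adjusted p 0.559 for each). Neither passed on Cy3 arrays (0.872 for each) or on Cy5 arrays (0.331 and 0.369). Without horse 1 neither list passed, with the proteasome median hardly moved at -0.099 (adjusted p 0.396) and the TCA cycle median at -0.092 (0.814), and without horse 4 the TCA cycle list did not (0.175, median -0.050). Dense arrays alone, where only horses 1 and 2 have both muscles, gave medians of -0.14 and -0.15 with calls (adjusted p 0.034 and 0.0201). Sparse arrays alone, where only horses 4 and 5 do, gave -0.079 and -0.31 without calls (0.521 and 0.351). No estimated correlation was run for these fits of 2 horses. An array-group term left the medians at -0.105 and -0.15 (0.0366 and 0.11), since the groups are balanced over the horse means and the term changes little but the spread. Without horse 4 the ribosomal and matrix lists passed at -0.11 and -0.066 (1.32e-08 and 0.0159), and without horse 5 the ribosomal list at -0.11 (0.00023). With an estimated correlation these calls were lost (0.636, 0.434 and 0.756). Without horse 4 endoplasmic reticulum stress genes passed at -0.069, 9 of 9 below 0 (0.0449, and 0.132 with an estimated correlation). The array groups, each with its own horses, parted here as in gluteus. The ribosomal median was -0.23 on dense arrays (51 of 56 below 0, adjusted p 6.47e-16) and 0.26 on sparse ones (39 of 54 above 0, 1.45e-05), and the matrix median -0.12 (0.0201) and 0.41 (0.0140). All 4 were called with the preset correlation, within fits of 2 horses each, and not tested with an estimated one.

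Single genes of the mean over muscles again stayed short of the threshold. Klf6, an injury-responsive transcription factor, was at -0.25 ± 0.057 (SE, n = 5), Col4a6, a basement membrane collagen chain, at -0.34 ± 0.082 (SE, n = 5), and Ckb, the brain-type creatine kinase, at -0.28 ± 0.084 (SE, n = 5). Fhl2, a LIM protein of striated muscle, at -0.27, the copper chaperone Atox1 at -0.33, Sh3pxd2b at -0.33, Casp2 at -0.25, Tspan9 at -0.24, Dnase1l2 at -0.24 and Mov10l1 at -0.21 were below 0 in every horse with a value. Above 0 stood Ankrd34a at 0.35 ± 0.10 (SE, n = 5), Uqcrc2, a core subunit of complex III, at 0.22 ± 0.082 (SE, n = 5) with 0.55 in horse 4, Wasf2 at 0.27, Gad1 at 0.23, Nubp1 at 0.23, Aldh16a1 at 0.21, Plcb4 at 0.20, C1qbp at 0.17 and Gpr6 at 0.16. Gmpr was at 0.27 over the 4 horses with both muscles, but horse 4, which lacks a gluteus value, had -5.42 in longissimus, and the longissimus mean of Gmpr was -0.85. Nubp1 likewise leaves out horse 4, at -0.53 in gluteus. Of other lists, Pfkm was at 0.26 ± 0.11, Pgam2 at -0.39 ± 0.17, Cpt1b at -0.19 ± 0.078, Cox6b1 at -0.14 ± 0.066, Myl3 at -0.27 ± 0.10, Stim1 at -0.17 ± 0.078, Camk2b at 0.18 ± 0.10 and the ribosomal proteins Rps9 at -0.32 ± 0.11 and Rps14 at -0.21 ± 0.088. Immune markers showed Cd68 at -0.25 ± 0.12 and Lck at 0.13 ± 0.058, with horse 4 alone for Cd68 (-0.81) and for Camk2b (0.61). Limma called 0 of 10063 features (lowest adjusted p 0.999), with 191 at an unadjusted p under 0.05, 52 above and 139 below 0, and 0 without variance moderation. Arrays of a single orientation called 2 (Cy3, Spesp1 at -1.20 and an unnamed probe) and 6 (Cy5, with Bmp8a at -4.73 and Psmb4 at -0.68), and sparse arrays 1 unnamed probe, all chosen after their values were seen. The 7 features called in a single orientation all had opposite signs in the other (Spesp1 at 1.37 in Cy5, Bmp8a at 3.88 and Psmb4 at 0.39 in Cy3). The interval lay inside a 2-fold change for 97.9% of features. Among other lists the fast fibre genes had a median of -0.13, the ribosomal genes -0.062 and calcium handling -0.025. Median, mean and test did not share a sign for 6 lists (slow fibre, extracellular matrix, regeneration, antioxidant, nerve and smooth muscle).

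The difference between the muscles, gluteus minus longissimus, asks where the ratio to the pool depends on the muscle. Neb (nebulin) at 0.44 ± 0.15 (SE, n = 5) and Myoz3, a Z-disc protein, at 0.32 ± 0.11 (SE, n = 4) had higher ratios in gluteus, as did Sh3pxd2b at 0.50 ± 0.14 (SE, n = 5), Grb14 at 0.49, Lrrc8c at 0.46, Ndn at 0.42, Fzd9 at 0.41, Cnp at 0.33, Npff at 0.33 and Nfe2 at 0.26. Calm2 at -0.61 ± 0.15 (SE, n = 5), Eif4h at -0.57 ± 0.10 (SE, n = 5), Eif4a2 at -0.67 ± 0.15 (SE, n = 5) and the myosin phosphatase subunit Ppp1r12a at -0.41 had lower ratios in gluteus, with Vps29 at -0.91, Magoh at -0.79, Rnf11 at -0.79, Wscd1 at -0.72, Tcf7 at -0.58 and Ugcg at -0.39. Members of the lists with the smallest p were Col4a1 at -0.46 ± 0.15, Idh2 at 0.31 ± 0.15, Pgam2 at 0.46 ± 0.28, Tnnt1 at 0.84 ± 0.41, Nfe2l2 at -0.30 ± 0.13, Cacna2d1 at -0.21 ± 0.10, Foxo1 at -0.33 ± 0.15, Uqcrb at -0.44 ± 0.23 and Rpl39 at -0.55 ± 0.29. None of these genes passed the threshold.

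Limma called 0 of 10176 features for the difference (lowest adjusted p 1), with 185 at an unadjusted p under 0.05, 81 above and 104 below 0, and 0 without variance moderation. The interval lay inside a 2-fold difference for 89.1% of features. None of the 22 lists passed. With the horse as a fixed replicate block, that is as a paired difference, the ribosomal protein list passed (adjusted p = 0.00509) with a median of -0.12 and 34 of 57 members below 0. No estimated correlation was run for this paired call. Its median differences were -0.44 and -0.47 in horses 2 and 3, against -0.0088, -0.028 and 0.072 in horses 1, 4 and 5. Horse 3 is dense in gluteus and sparse in longissimus. The adjusted p of the ribosomal list in the unpaired fit was 0.606 (0.883 with an estimated correlation). Without horse 4, 4 lists passed, with medians of -0.21 for ribosomal proteins (adjusted p 1.80e-05), -0.11 for extracellular matrix (0.0109), -0.15 for the proteasome (0.0132) and 0.10 for the respiratory chain (0.0113), and with an estimated correlation none of the 4 passed (0.741, 0.468, 0.468 and 0.741). Fast fibre genes had a median difference of 0.21 and glycolysis one of 0.12. Median, mean and test did not share a sign for 3 lists (calcium handling, macrophage, proteasome). Each muscle has its own pool, so a difference between the pools is part of every value here.

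Across the 10176 features the mean ratios of the muscles correlated at 0.30 (Pearson) and 0.16 (Spearman), and 55.2% of features had the same sign. This is a correlation across genes of the same 5 horses, and genes are not independent replicates. It was 0.53 and 0.56 between arrays of the same dye orientation and -0.23 and -0.31 between arrays of opposite orientation. At an unadjusted p under 0.05 in both muscles there were 13 features, where independent muscles would give about 7.8, and 8 of the 13 had the same sign. Between horses of 1 muscle the correlation of ratios ran from -0.60 to 0.51, and 12 of 20 such pairs lay below 0. The lowest were longissimus horses 1 and 2 at -0.60 and gluteus horses 2 and 4 at -0.42. Between the muscles of 1 horse it was 0.54 in horse 1 and at most 0.18 in the others.

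**Figure D3:**
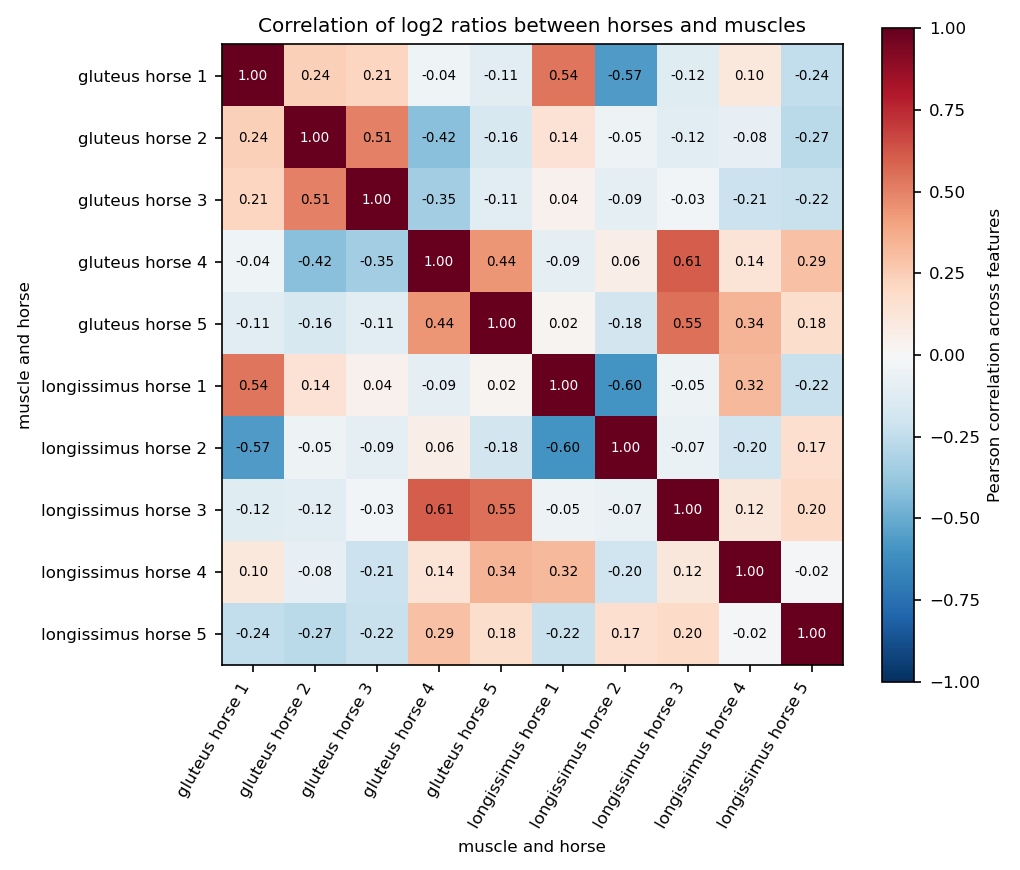
Pearson correlation across features (colour and number) between the log2 ratios of each horse and muscle (both axes), after averaging the dye-swapped arrays. Longissimus horse 2 runs against horse 1 in both muscles (-0.57 and -0.60), while gluteus horses 4 and 5 and longissimus horse 3, all on sparse arrays, correlate at 0.44 to 0.61.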

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

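The tests of dye bias, of exchanged labels, of horses alike in both muscles, of the sign patterns by comparison, of the array group as a term, and of the proteasome and TCA cycle lists were chosen only after the result was seen. The test for a horse standing apart and the splits of the samples were not. A horse stands apart here when its gap to the nearest other horse exceeds Dixon's 95% limit for the range, which chance alone gives in about 5% of groups. Of 200 sets tested (156 genes and 44 list medians), 24 had such a horse, and in 20 of them it was horse 4.

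Horse 4 stood apart for 11 named genes in longissimus. It stood at -3.09 for Sdhc, -2.12 for Ndufb7, -4.56 for Ndufs3, -2.95 for Tnnt3, -1.63 for Hrc, -2.41 for Psmd8, -4.10 for Rpl10 and -1.93 for Cd68, and at 0.371 for Cacna2d1, 1.05 for Psmd12 and 1.51 for Ssbp2. In the mean of both muscles it stood at -1.81 for Sdhc, -0.814 for Cd68, 0.611 for Camk2b and 0.547 for Uqcrc2. In gluteus it stood at -0.535 for Des and at list medians of 0.235 (macrophage), 0.0818 (regeneration) and 0.245 (nerve), and in longissimus at -0.54 for the macrophage list. Its longissimus arrays hold 8966 and 11275 values, 2 of the 3 lowest numbers. The log2 ratios on them were also widely spread, with median absolute deviations of 0.64 (Cy3) and 0.54 (Cy5). Those of longissimus horse 1 were 0.79 and 0.57, and those of longissimus horses 2, 3 and 5 lay between 0.21 and 0.37. The values above come from arrays not scaled to a common spread. Whether horse 4 stands apart after such scaling was not tested. Other horses stood apart for Eif4h in gluteus (horse 2, -0.245), Tcf7 in gluteus (horse 3, -0.427), Plcb4 in both muscles (horse 5, 0.109) and the nerve list in longissimus (horse 1, -0.262).

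Horses compared with the same pool had opposite ratios, most of all longissimus horses 1 and 2. The correlation stayed at -0.599 after the dyes were averaged, which argues against a dye effect of equal size on both arrays of a pair. An unequal effect does not cancel in the average, so this value cannot decide on it. In longissimus horse 1 the shared dye pattern correlated at -0.472 with the Cy3 array and at 0.185 with the Cy5 array. Horses that differ alike in both muscles are argued against for the 5 horses as a set, since 1 of 5 horses had a correlation above 0.3 between its muscles. For horses 1 and 2 this count cannot decide. Their muscles correlated at 0.54 and -0.049, and after removal of the muscle means at 0.58 and 0.304. Exchanged dye labels between the longissimus arrays of horse 1 or horse 2 may explain it. Arrays of opposite labelled dye correlated at -0.522 and -0.525, below the horses' own pairs (-0.269 and -0.322). Their arrays of the same labelled dye correlated at 0.33 (Cy3) and 0.192 (Cy5), as a dye effect shared by the horses would also give. Horses with truly opposite ratios could give all of these values too, so exchanged labels stay open.

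Fewer features than chance gives reached an unadjusted p under 0.05 in gluteus (187) and longissimus (426), where about 509 are due. With each muscle fitted alone the counts were 510 in gluteus and 147 in longissimus. The gluteus shortfall thus appears with the spread shared by both muscles, and the longissimus one does not depend on it. The sign pattern of the horses was set against 15 other patterns, of which opposed horses would raise only those near their own split. A count of patterns therefore cannot settle it in gluteus, where the highest count, 842, was that of dense against sparse horses. There 3 of 15 other patterns gave at least 1.5 times the real count, fewer than the prediction asks. In longissimus 7 did, too near 50% to decide (highest 2257, horses 1 and 4 against the others, and 2 patterns called up to 11 features). In the mean of both muscles (191 features) 10 did, so the sign pattern of the horses may account for the low count there. The array group as a term left 3.3% and 4.1% in gluteus and longissimus, under the 5% that the prediction asks. It raised the count in gluteus from 187 to 336 and left that in longissimus at 417. The term is 1 effect common to both muscles, so this argues only against such a common effect as the whole of it. An array-group effect that differs between the muscles was not fitted and stays open. No biological explanation was tested.

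The proteasome and TCA cycle lists lay below 0 in the mean of both muscles. Correlation between the genes of a list is a candidate explanation, as the lower adjusted p of the 2 was 0.318 with the correlation estimated. Dye bias is argued against for the proteasome list, as the mean over horses was below 0 by more than its standard error in 2 of 2 orientations (-0.12 ± 0.046 in Cy3, -0.13 ± 0.10 in Cy5). For the TCA cycle list it was so in 1 (-0.13 ± 0.12, -0.16 ± 0.16), and since an equal dye effect cancels in the average only an unequal one stays open, as the distance of each orientation from a horse's average (0.13 ± 0.033, mean over horses) was near the size of the average (-0.15). The array group cannot be told apart for either list, because 0 muscles had opposite signs on dense and sparse arrays beyond the standard error and the horses of a group are few (gluteus proteasome -0.18 ± 0.024 dense and 0.018 ± 0.024 sparse). A lower expression in RER muscle stays open, untested apart from these.

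For the difference between muscles, chance could not be excluded. Of 100 splits of the 10 values (126 possible), 69 gave at least the real 185 features at an unadjusted p under 0.05, and the highest other gave 2711. Of 12 splits that part every horse's pair like the real one, 6 gave as many, and the highest other gave 898. The split by array group gave 1598 features with 11 past the adjusted threshold, a structure of the samples that the muscles do not share.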

How the results depend on the processing

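The turned orientation, the dense-only, sparse-only and array-group settings and the floored values were tests chosen only after the data were seen, and the others were planned. The turned orientation is also the planned rule read pair by pair, which was not kept as the main setting. For limma counts of 0 adjusted calls, an unadjusted p under 0.05 gave 187 features in gluteus, 426 in longissimus, 191 in both and 185 in the difference. Arrays with RER RNA in Cy3 called 2, 2 and 2 features in gluteus, longissimus and both, and those in Cy5 4, 89 and 6, with 2 named genes past the threshold, while the difference stayed at 0. Sparse arrays alone called 1, 2 and 1. The other settings left all 4 counts at 0, including each horse left out (0 to 0), the turned orientation (138, 1653, 1311 and 343 at an unadjusted p under 0.05) and no variance moderation (572, 192, 207 and 518). With the horse as a random replicate block (correlation 0.201) or a fixed one (paired difference) the counts also stayed at 0. Gene lists past the threshold numbered 1 in gluteus and 2 in both muscles, and 0 in each with an estimated correlation, with fry by direction or mixed, with Cy3 arrays and with Cy5 arrays. Turning the arrays gave 4 other lists in gluteus, without the proteasome, and 0 in both. Dense arrays gave 4 in gluteus, 1 in longissimus, 7 in both and 4 in the difference, sparse arrays 2 in gluteus, 2 in both and 2 in the difference, and the array group as a term 1 in both. For the mean of both muscles the dense and the sparse fit hold 2 horses each. With the horse as a fixed replicate block (paired) the difference had 1 list, not tested with an estimated correlation. With 1 horse left out the list counts ran from 0 to 4 in gluteus, 0 to 1 in longissimus, 0 to 4 in both and 0 to 4 in the difference. The gluteus proteasome median reversed to 0.0072 on sparse arrays. The correlation between muscles, 0.30, reversed to -0.23 (gluteus Cy3 with longissimus Cy5) and -0.31 (gluteus Cy5 with longissimus Cy3). Of the 20 genes named by rule per comparison, 16, 18, 15 and 14 kept their sign in every setting run.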

Other observations

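The tests in this part were all chosen only after the data were seen. On sparse arrays alone 380 probes had values, and they include genes of mitochondrial DNA that the comparisons above could not test and further probes for calcium genes tested there by another probe. Averages here are over 3 horses, horses 4 and 5 as the mean of both muscles and horse 3 as longissimus alone. ATP2A1, the calcium pump of the fast-fibre sarcoplasmic reticulum, averaged -0.80 with a standard deviation of 0.18 over 3 horses and was below 0 on 10 of 10 arrays (limma over 6523 features, adjusted p = 0.138). The probe tested above, Atp2a1, averaged 0.20 on the same arrays (0.076 in gluteus and 0.12 in longissimus over all horses), so the direction of this transcript is not settled. Which probe matches the horse transcript better was not tested. SLC8A1, the sodium-calcium exchanger, averaged -0.36 and was below 0 on 10 of 10 arrays (adjusted p = 0.338), and the probe tested above, Slc8a1, averaged -0.055 on them.

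Of the mitochondrially encoded genes, ND6 averaged -0.89 with a standard deviation of 0.24 (below 0 in 19 of 20 probe values, adjusted p = 0.155), ND5 -0.53 with 0.091 (18 of 20, 0.173) and ND3 -0.37 (17 of 20, 0.347). ND1 at 0.075, ND2 at 0.21, ND4 at 0.0040 and CYTB at 0.10 did not follow, and ND4L at -0.51 with a standard deviation of 0.70 was below 0 in 14 of 20 values. The list of 8 members had a median of -0.18, with 4 members below 0, and camera gave it a p of 0.0766 without adjustment. PRDX1, an antioxidant enzyme, averaged -0.52 (9 of 10 arrays below 0, adjusted p = 0.176), while LUM at 1.14 (0.401) and ITGB2 at 0.58 (0.407) were above 0 on all 10 arrays and HK2 averaged 0.40 (0.350). Other members of their lists stood at -0.15 (PRDX6), 0.34 (TXN), 0.29 (COL1A1), -0.12 (CD14) and -0.096 (LDHA). The other probe for Lum averaged 0.34 and was below 0 in 2 of 3 longissimus samples. For Itgb2 the other probe averaged 0.097, with -0.043 and -0.0059 in longissimus horses 4 and 5 and values above 0 in the other samples. Horse 4 had the highest gluteus and longissimus values of LUM (2.96 and 1.46) and of ITGB2 (1.67 and 0.61).

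Over the 3 horses with sparse values, with horse 3 in longissimus alone and the others as the mean of both muscles, 7 features passed an adjusted p of 0.05, all below 0 in 3 of 3 horses. They include Pnma2 at -1.82, the kinase PRKCA at -2.04 and Rhbdl2 at -1.65, and 4 unnamed probes. For 44 genes with both such a probe and another, 29 had the same sign, with a Pearson correlation of 0.34 across genes.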
